A study of Mus musculus with 2 samples.

How the data were processed

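Total RNA from the left ventricle of 1 mouse with transverse aortic constriction (TAC) and 1 mouse with a sham operation was profiled on 1-colour (Cy3) Agilent arrays of a custom mouse piRNA design, 1 array per mouse. TAC narrows the aorta surgically, so that the left ventricle pumps against a higher pressure and thickens. Both hearts were taken 4 weeks after surgery. piRNAs are small RNAs that bind PIWI proteins and are best known for silencing transposons in the germline. Per the labels' protocols, Cy3-labelled cRNA was made from total RNA with a Quick Amp kit. As background, that kit's standard primer binds poly(A) tails. The labels do not say whether small RNAs were tailed or selected first, so whether a probe read a mature piRNA or a longer transcript that holds its sequence is not given in the sources used here.

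The scanner files hold linear fluorescence intensity values that the authors obtained with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes and the file headers. The processed intensity is background-subtracted, spatially detrended and held at a small positive surrogate where a spot was not above background, per the file headers. Feature Extraction also deposited an error for each spot and its yes-or-no flags for signal above background, saturation and outliers, as coded in columns of other kinds. Each array carried 42486 spots, of which 41069 were piRNA probes with 1 spot each and 1417 were control spots. The header names the mouse mm9 build, but gives no coordinates. The files name a piRNA probe by its array ID alone. Of the 41069 IDs, 0 matched a symbol, synonym, locus tag or RefSeq accession of the gene table used here (GRCm38.p6). No piRNA name, sequence, position or host gene is therefore given, and the lists of host genes, sequence features and piRNA clusters that had been fixed were not used.

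The deposited series table holds log2 values for 12601 of the probes, and a second deposited table adds 16 control probes to the same values. The authors' normalization is not given in the sources used here. Quantile normalization of log2 processed intensity over all 41069 piRNA probes came within 0.0207 of every value in the table, with a median absolute difference of 0.000375. The 12601 probes were the same set as the probes well above background, and not an outlier, on at least 1 array. Column medians were 6.21 for TAC and 6.22 for sham.

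For the main values, log2 processed intensity was taken relative to each array's 75th percentile over the probes measured on both arrays, since only a minority of the probes was detected (25.2% and 24.2%). A probe counted as measured when Feature Extraction called it well above background, not saturated and not an outlier on both arrays. The 75th percentiles were 825.7 fluorescence units on the TAC array and 390.1 on the sham array, a 2.12-fold gap that the scaling removed. A difference of at least 2-fold was used as a rule of size. With 1 array per group no test between conditions was possible, so no p-value is given and no difference has a replicate check. The arrays were scanned on different days, so scan day and group cannot be told apart. The error printed beside a single probe combines the Feature Extraction errors of its spot on each array, on the log2 scale. It covers the scanner and spot only, not the spread between mice, hybridizations or labelling reactions.

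A probe well above background on 1 array only has a bound. The bright array's scaled value was set against the dim array's scaled value of either the lowest signal among probes well above background or the probe's own signal, whichever was higher. The count and scaling steps were tested on simulated data. The simulated 4-fold differences and the simulated shift between arrays were recovered. The simulated shift was the same for all probes, and few probes changed, as many up as down. The simulation therefore checks the arithmetic, and cannot show which scaling is right for these arrays.

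The rule for named probes, fixed before the data were examined, as were the comparisons and most alternatives, took the 10 probes with the largest differences in each direction, the 5 brightest per array and the 3 largest bounds per array, plus 1 piRNA given by accession, which was not analysed here. Because the IDs carry no names, at most 2 IDs per direction and the brightest ID of each array are printed, and the others are given as ranges. Alternatives covered the background correction, the scaling, the detection rule, the threshold and the authors' table. Normexp was run on median spot and background signals with an offset of 50. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and, for normexp, quantile and cyclic loess normalization, limma 3.58.1 in R 4.3.3.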

Results

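To look for piRNAs that differ in pressure-overload hypertrophy, left ventricular RNA of 1 TAC mouse was compared with that of 1 sham-operated mouse at 4 weeks. Each array carried 41069 piRNA probes and 153 negative control spots. The median processed intensity of these control spots was 7.58 fluorescence units on the TAC array and 5.06 on the sham array. The sham value was also the sham median over all piRNA probes. Spots not above background are held at a surrogate, so these medians are not readings of the background itself. The median background signal over all spots was 23 units on the TAC array and 25 on the sham array. The lowest piRNA signals called well above background were 27.8 and 25.2 units. No piRNA probe was saturated, and outlier flags fell on 139 TAC and 53 sham piRNA probes. With 1 array per group, scanned on different days, each difference is one between these 2 arrays.

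About as many piRNA probes gave signal in both hearts. On the TAC array 10366 probes (25.2%) were well above background, and on the sham array 9939 (24.2%). Both arrays detected 7704 probes, the TAC array alone 2638 and the sham array alone 2151, leaving out probes flagged as outliers on the other array. The signal was concentrated in few probes. The 100 brightest carried 49.5% of the summed piRNA signal on the TAC array and 54.9% on the sham array, and 83 of those 100 were shared.

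The brightest probe of the TAC array was ASPI224694P, at 478647 units against 464247 on the sham array. ASPI107239P was the brightest of the sham array, at 495061 units against 430261 on the TAC array. Of the 5 brightest probes, 4 were the same on both arrays. Relative to the 75th percentile, the 5 brightest of each array lay 1.04 to 1.28 lower in TAC on the log2 scale, with a scanner error of 0.204 each. The direction turned under some scalings for 3 of these 6 probes. In the authors' deposited table ASPI224694P was 0.10 higher in TAC and ASPI107239P 0.14 lower. Over the 100 brightest measured probes the SD of the difference was 0.26, the narrowest of any signal range examined, around a median of -0.83. Of these 100 probes, 31 were at least 2-fold lower in TAC and 0 at least 2-fold higher. The scaling took 1.08 off every log2 difference, more than the median of -0.83 lies below 0. Before scaling the median of these 100 probes was therefore higher in TAC, so the direction of this split depends on the scaling.

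Among the 7704 probes measured on both arrays, 1300 (16.9%) were at least 2-fold higher in TAC, 1908 (24.8%) were at least 2-fold lower and 4496 (58.4%) lay between. The difference had a median of -0.16, an SD of 1.63 and a central 95% range of -3.95 to 3.09 on the log2 scale. Across probes, which are not independent replicates, the arrays correlated with Pearson's r = 0.83 and Spearman's rho = 0.71. The median scanner error of a difference was 0.23. After 2 such errors were taken off each difference, 766 probes were still at least 2-fold higher and 1127 at least 2-fold lower.

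**Figure D1:**
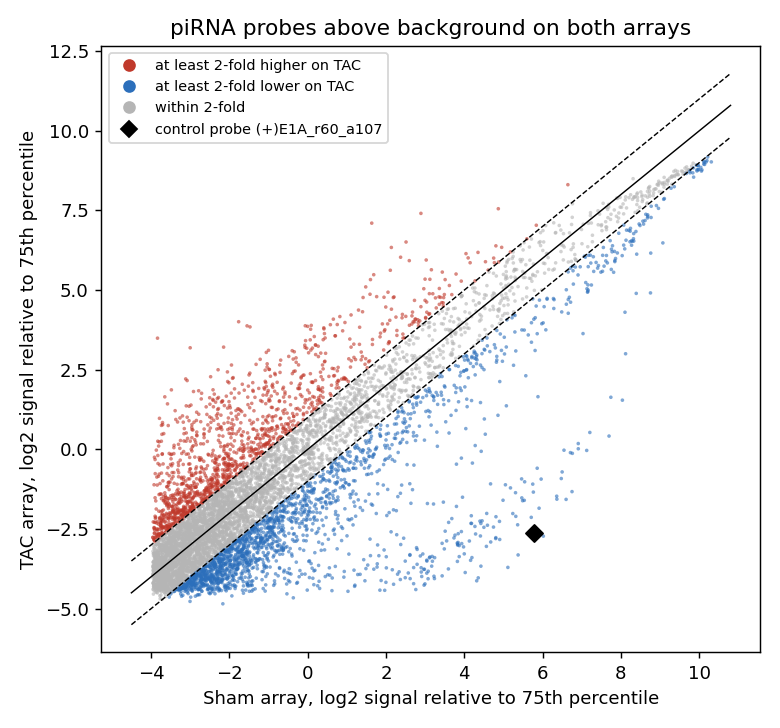
Log2 signal relative to the 75th percentile on the TAC array (vertical) against the sham array (horizontal) for the 7704 piRNA probes measured on both, 1 point per probe, with lines of equality and of 2-fold difference. A separate cloud of probes lies far below the diagonal. The 152 probes at least 32-fold lower had a median 102-fold weaker signal in TAC. The control probe (+)E1A_r60_a107 (diamond) lies on the side of the cloud far from the diagonal.

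The split between higher and lower probes depended on how the arrays were scaled. Before scaling, the median measured probe was 0.92 higher in TAC on the log2 scale, and 3647 probes were at least 2-fold higher against 554 lower. Setting that median to 0 gave 1585 higher and 1607 lower. Quantile normalization gave 1850 higher and 1339 lower, so that 58.0% of the 2-fold differences were upward instead of 40.5%. Under the 75th percentile of all probes the counts were 1987 and 1292, and under scaling on 12 positive control probes they were 714 and 3116. With cyclic loess they were 1404 and 1653. A set of 606 probes was at least 2-fold higher, and another of 554 at least 2-fold lower, under every one of the 8 settings of scaling and background. Several of these settings shift every probe by 1 constant, so their calls are nested and do not check each other. The 554 are the same probes called lower with no scaling.

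**Figure D2:**
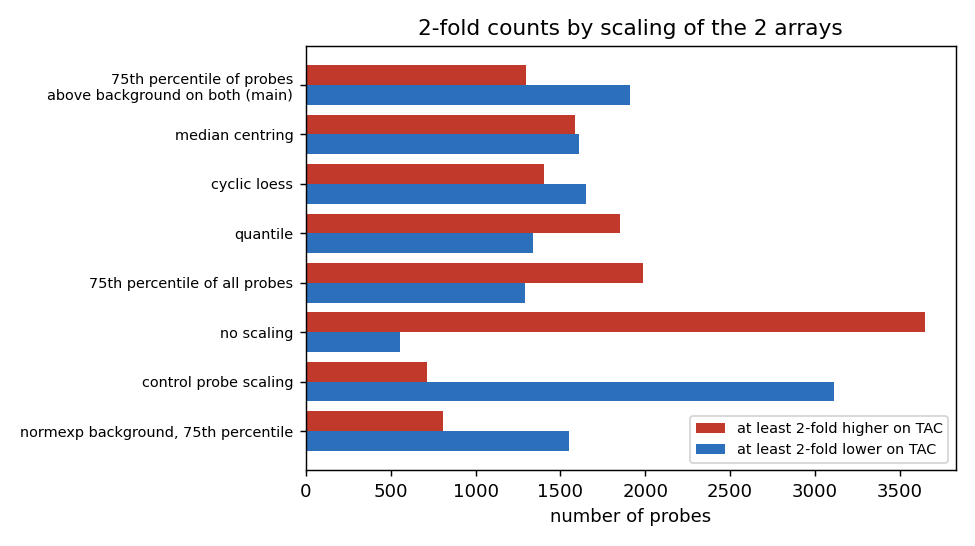
Number of measured piRNA probes (horizontal, out of 7704) at least 2-fold higher (red) or lower (blue) on the TAC array under 8 settings of scaling and background. The lower probes outnumber the higher ones at 1908 to 1300 in the main setting and are outnumbered at 554 to 3647 with no scaling.

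The probes furthest above their sham level in TAC were ASPI335456P and ASPI341827P. ASPI335456P read 9298 units in TAC against 27.4 in sham, a scaled difference of 7.33 ± 0.33 (scanner error, 1 array each) on the log2 scale, or 160.5-fold. ASPI341827P read 7541 units against 48.8, a difference of 6.19 ± 0.25, or 73.0-fold. The 10 probes furthest up differed by 5.30 to 7.33, from sham signals of 27.4 to 1214 units. Their differences lay between 3.86 and 8.41 under every scaling, under normexp and in the authors' deposited table.

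In the other direction, ASPI089307P read 63.4 units in TAC against 13510.5 in sham, a difference of -8.82 ± 0.27, or 450.7-fold. ASPI390132P read 125 units against 25308, a difference of -8.74 ± 0.22, or 428-fold. The 10 probes furthest down differed by -8.82 to -7.89 and lay between -9.37 and -6.66 under those same alternatives. Relative to the median probe, the 4 named differences were 7.49, 6.35, -8.66 and -8.58.

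Among the probes measured on both arrays, 217 were higher and 276 lower in TAC at 8-fold or more. At 16-fold these were 52 and 191, and at 32-fold 12 and 152. Probes detected on 1 array only were left out, with bounds up to at least 255-fold lower and at least 67.6-fold higher. The 152 probes at least 32-fold lower held a second peak of the distribution, along with the sparser bins between that peak and the cut. The 0.5-wide bin from -7.0 to -6.5 held 48 probes and the bin from -6.0 to -5.5 held 13. The median difference of the 152 probes was -6.67 (interquartile range -7.16 to -6.22), or 102-fold. Their median signal was 103 units in TAC and 5557 in sham. The number at least 32-fold lower ran from 119 to 169 over the 8 settings, against 3 to 60 for those at least 32-fold higher. The control probe (+)E1A_r60_a107, named after an adenoviral gene, differed the same way. It read 135 units in TAC and 21369 in sham, a scaled difference of -8.39, with spot SDs of 0.08 over the 30 TAC spots and 0.08 over the 31 sham spots that were not outliers.

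**Figure D3:**
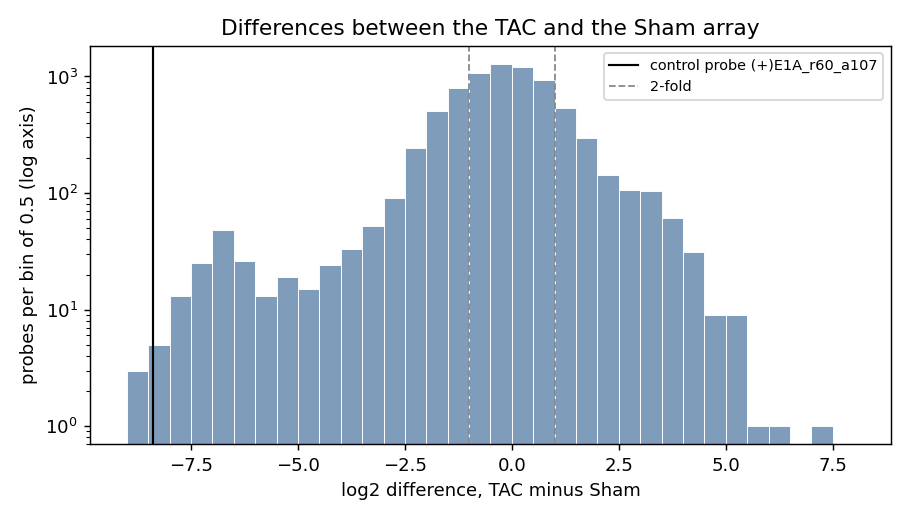
Number of measured piRNA probes (vertical, log axis) per 0.5-wide bin of the log2 difference between the TAC and the sham array (horizontal), with dashed lines at 2-fold and a solid line at the control probe (+)E1A_r60_a107. The second peak at -7.0 to -6.5 holds 48 probes, and no such peak stands on the upper side.

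The spread of the differences was larger in the brighter bins. In 5 equal bins of mean signal, the SD of the difference was 0.73 in the dimmest bin, 1.14 and 1.49 in the next ones, 2.24 in bin 4 and 2.03 in the brightest. The bins use the mean of both arrays, so a probe bright on 1 array and dim on the other falls between its signals. In bin 4, 27.3% of probes were at least 2-fold higher and 25.2% lower. In the dimmest bin these shares were 2.47% and 21.5%. The requirement that a probe be above background on both arrays limits how far dim probes can differ. It also bears on the direction. The lowest signals well above background were close before scaling, at 27.8 units on the TAC array and 25.2 on the sham array. The scaling removed a 2.12-fold gap, so probes near both limits read lower in TAC. The split in the dimmest bin therefore follows at least in part from the scaling. Over the 6 control probes that had 10 or more spots and were well above background on both arrays, corner marks left out, the spot SD on the log2 scale was 0.07 to 0.13 on the TAC array and 0.08 to 0.15 on the sham array. That is the spread within an array. Between the arrays, the scaled differences of the 12 measured positive control probes had an SD of 2.65, and of 0.84 over the 11 without (+)E1A_r60_a107.

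Probes seen on 1 array only had bounds of unequal size. Of the 2151 probes detected in sham alone, 1972 (91.7%) were at least 2-fold lower in TAC by the bound, and 468 at least 8-fold. The 3 largest bounds were at least 255-fold, at least 217-fold and at least 217-fold lower. Of the 2638 probes detected in TAC alone, 416 (15.8%) were at least 2-fold higher by the bound, and 46 at least 8-fold. The 3 largest were at least 67.6-fold, at least 41.8-fold and at least 37.3-fold higher. These counts carry the 2.12-fold gap between the arrays' 75th percentiles, which raises the sham bounds and lowers the TAC bounds. All 2151 sham bounds were over 1-fold, against 1494 of the 2638 TAC bounds. The shares at 2-fold therefore follow largely from the scaling.

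The authors' deposited table of 12601 probes had 3908 probes at least 2-fold higher in TAC and 3219 lower. Of its probes, 4789 (38.0%) were well above background on 1 array only, and these gave 3876 (54.4%) of its 7127 differences of at least 2-fold. Over the 7704 probes measured on both arrays, the table held 1850 higher and 1340 lower. Its ranks within each array were those of the processed intensity (Spearman's rho of 1 across probes on each array).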

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

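Of the tests below, those of scaling, of scanner noise, of scan day, of a spike-in mix and of the spread of the control spots were chosen only after the result was seen, and the others had their outcomes written down first. No group holds enough arrays for a sample to be picked out as far from the others.

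The control probe DCP_20_9, which lies outside the piRNA comparisons and enters only the scaling on control probes, gave a signal above its sham level. Its 2 spots read 410.5 units on the TAC array and 67.3 on the sham array, 1.53 higher in TAC on the log2 scale after scaling. The other 4 DCP probes that were measured on both arrays lay 0.68 to 0.90 higher.

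One pattern is that more probes were lower than higher in TAC among those at least 2-fold apart. A trend of the difference with position on the array was not decided: with the median of each of 16 array blocks set to the overall median, the lower to higher ratio was 1.46, against 1.47 before, but the ratio follows the overall median, which that step leaves as it was. The scaling between the arrays could account for the direction of the split, since the higher share of the differences was 40.5% in the main setting and ran from 18.6% to 60.6% over 4 other scalings, unscaled arrays and median centring left out. A lower level of more piRNAs after TAC surgery was not tested.

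A further pattern is the 243 probes at least 16-fold apart, 191 of them lower in TAC. A local defect on one array is argued against, since 22.2% of them had another within 3 rows and 3 columns, inside the central 95% (16.05% to 30.9%) of 1000 random draws. Scanner noise of dim spots was not decided. Measured probes had to be well above background on both arrays, which limits their error in advance. The largest scanner error over all 7704 measured probes was 0.448 on the log2 scale. A 16-fold difference is thus at least 8.93 errors, as Feature Extraction estimated them. Surgery, mouse, array, labelling and scan day cannot be told apart, because each group has 1 array, scanned on its own day, and 0 comparisons within a group exist to weigh array or scan day rather than surgery.

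The last pattern is the control probe (+)E1A_r60_a107, 335-fold brighter on the sham array after scaling. Among piRNA probes measured on both arrays, 152 were at least 32-fold brighter there. A spike-in mix added to the sham RNA alone was not decided. After scaling, 7 of the 10 E1A control probes were brighter on the sham array, but 1 before it. That count cannot decide, since most of the 7 were not well above background on either array. The negative control spots also lay at -0.51 after scaling. Well above background on most spots were 2 E1A probes on the sham array and 3 on the TAC array. Besides (+)E1A_r60_a107, (+)E1A_r60_a22 was so on both arrays and (+)E1A_r60_3 on the TAC array. They were 1.91-fold and 2.85-fold brighter on the TAC array after scaling. A local defect is argued against by the spot SD of 0.0765 of (+)E1A_r60_a107 on the sham array. An RNA or labelled product in one sample that binds some probes stays open: 4 piRNA probes had at least the same excess, and without probe sequences no match could be looked for. A candidate explanation for the second peak is such a product in the sham hybridization, and a lower level of these RNAs after TAC surgery is the untested alternative.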

How the results depend on the processing

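Normexp on median signals, subtraction of scanner errors, block medians set to the overall median and the authors' table limited to probes above background on both arrays were chosen after seeing the data. The direction and the 2-fold size of the 20 probes furthest up or down held in all 9 settings run on them. These probes were picked as the extremes of the main setting, 5.30 or more apart on the log2 scale, so little else was possible. The counts did not hold. Probes higher in TAC numbered 808 with normexp on median signals, 1987 with the 75th percentile of all probes, 2063 at 1.5-fold and 766 with 2 scanner errors subtracted, where 1127 were lower. No scaling gave 3647 higher and 554 lower, control probe scaling 714 and 3116, and the 4-fold threshold 465 and 609. There were 3908 higher and 3219 lower in the authors' table, which also holds probes above background on 1 array. Probes above background on at least 1 array gave 2903 and 3951, and no detection filter 3878 and 6978. Both rules counted more probes, 12493 and 40901. Without the filter the median difference was -0.49, near the -0.51 of the negative control spots. What else moved these counts was not tested. Among probes brighter than the median, 1013 were lower, since fewer probes were counted. The remaining alternatives, among them quantile, median centring and cyclic loess, stayed within 1.5 times. With the laxer call of a positive and significant signal, 19689 probes were detected on TAC and 19365 on sham, 4083 and 3689 of them on that array alone. Among the brightest probes, the difference turned from lower to higher in TAC for ASPI224694P (0.10 with quantile and in the authors' table, 0.0441 with no scaling), for another of them (0.0242 with quantile and in the authors' table) and for 1 more (0.0674 in both, 0.0034 with no scaling). The cause of these reversals was not tested beyond the scaling itself. Leaving out a replicate, medians over spots of a probe and list comparisons were not run, since each group has 1 array, each probe 1 spot and no probe a name. Normexp on mean signals was not run, since the files used hold medians. No paired analysis was possible because each group has 1 array. Signal over background limits the dim probes, where only bounds can be given.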

Other observations

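The test below was chosen after its result was seen. The distribution also had a shoulder on the upper side, with 106 probes between 2.5 and 3.0 and 104 between 3.0 and 3.5, before it fell to 61 in the next bin.

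Probe numbers carry no annotation here, but related sequences could have been numbered together. If probes with close ID numbers measured related piRNAs, their differences should go together. Over 416 pairs of measured probes 1 to 3 numbers apart, the correlation of the differences was 0.083 across probe pairs, inside the central 95% range of -0.10 to 0.095 of 1000 shuffled orders. The hypothesis was not borne out at this number of pairs.

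The control probes measured on both arrays did not share 1 shift. After scaling, the 4 ETG and eQC probes lay between -0.53 and 0.43, the 5 DCP probes between 0.68 and 1.53, and the bright corner spots at -1.37. Scaling on controls therefore depends on which are taken.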
